A study of Gossypium hirsutum with 89 samples.

How the data were processed

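Transcript levels were measured on 89 Affymetrix Cotton Genome arrays hybridised with RNA from 5 field-grown genotypes of upland cotton, Gossypium hirsutum. The labels class JKC 725 and JKC 777 as superior in fibre traits and JKC 703, JKC 783 and JKC 737 as inferior. Each genotype was sampled at 0, 6, 9, 12, 19 and 25 days post anthesis (dpa), with 3 biological replicates per genotype and day, except that JKC 783 had 2 at 25 dpa. Whole ovules were taken at 0 dpa and fibre alone at the later days, so the step from 0 to 6 dpa also changes the tissue. Per the labels, total RNA was labelled as biotin cRNA and no replicates were pooled.

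The deposited table holds 1 intensity per probe set and array, which the authors made with MAS5 (version not stated). These intensities are on a linear scale and were scaled by the authors so that the 2% trimmed mean of each array, recomputed here, was between 500.091 and 500.188. No other normalization between arrays is stated. The table has 24132 probe sets. The median signal of an array lay between 59.94 and 119.8 and the 10 brightest probe sets took 0.621 to 1.81% of an array's signal. The number of arrays limits the precision.

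Values were converted to log2 of the signal plus 4.38, the 10th percentile of the table. The 103 control probe sets whose identifiers start with AFFX were left out, which left 24029. A probe set was tested when the mean of at least 1 of the 30 groups of genotype and day reached the 40th percentile of the table, a signal of 40.4. This left out 5370 probe sets and kept 18659. A first run had also left out 56 reporter and ribosomal RNA probe sets, and the planned rule was restored after its counts had been seen.

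The design, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where a choice is said to have been made later. All models were fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 30 groups, an intensity trend in the variance prior and Benjamini-Hochberg adjustment over the tested probe sets. Stage steps were averaged over the 5 genotypes, and so was the transition, which is the mean of 19 and 25 dpa minus the mean of 6, 9 and 12 dpa. A probe set was called in these at an adjusted p under 0.05 and a change of at least 1 on the log2 scale. The classes were compared in limma on the 5 genotype means, 2 against 3, so that genotypes and not arrays were the replicates, with an adjusted p under 0.05 and no minimum change. Differences among the 5 genotypes on each day were tested by limma's F test with an adjusted p under 0.05 and a range of at least 1 on the log2 scale. The genotype by stage interaction over the 5 fibre stages was tested by an F test without a minimum change.

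Gene names were taken from a table that pairs probe sets with RefSeq genes and from the synonyms of the RefSeq annotation of assembly Gossypium_hirsutum_v2.1. It named genes for 743 probe sets, 697 of them with 1 gene and 46 with several, and left 23389 unnamed. A readable synonym existed for 324 probe sets of 246 genes, and 300 of these, of 235 genes, were tested. Only these 1.61% of the tested probe sets could be named, so the genes given by name are a small part of each count. Where a gene has several synonyms, 1 of them was used throughout. Probe sets whose identifiers end in x_at or s_at can bind transcripts of more than 1 gene, including the copies in the A and D subgenomes.

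Genes named for a stage step or for the transition are the 5 with the largest rise and the 5 with the largest fall among called, nameable probe sets that moved the same way in all 5 genotypes, so each such change held its direction in 5 of 5 genotypes. Fewer are named where fewer met the rule. For each gene list, up to 2 called members with the largest change in the transition and the member with the highest mean are named. For the classes, probe sets whose 2 superior genotypes both lay above or both below the 3 inferior ones, with an adjusted p under 0.05 when arrays were counted as replicates, are named up to 10 in each direction over the fibre stages and 5 in each direction per day. For differences among genotypes, the 5 with the largest range are named. Any other gene given was chosen after its values had been seen.

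The lists covered cellulose synthases (of the secondary wall, and all), cellulose deposition partners, lignin-like and secondary wall polymer genes, fasciclin-like arabinogalactan proteins, expansins, xyloglucan endotransglucosylases, pectin modification, tubulins, the actin cytoskeleton, very long chain fatty acid synthesis, lipid transfer proteins, sucrose cleavage, turgor and vacuole, ethylene synthesis, auxin response, brassinosteroid and gibberellin, reactive oxygen scavenging, class III peroxidases, glutathione S-transferases, flavonoid synthesis, phenylpropanoid and monolignol synthesis, and MYB, HD-ZIP, NAC and WRKY factors. They also covered annexins and 14-3-3 proteins, ribosomal proteins, heat shock proteins, the proteasome, protein breakdown, calcium signalling, fibre-named genes, and markers of dividing ovule cells, of seed and embryo, of photosynthetic tissue, of fibre cells and of pollen and flower parts. The 19 lists with at least 3 tested probe sets were tested with camera of limma, with a preset correlation of 0.01, in 6 stage contrasts and the class comparison over the fibre stages, and the 133 p-values were adjusted together. Each test was repeated with the correlation estimated from the data. In all 133 tests the number of list members called was the same when adjusted over the list alone.

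The scripts were tested on simulated data with the observed means and spreads, in which 100 probe sets each changed by 1.5 and by 3 on the log2 scale among 18659. For the stage tests the changes were planted alike in all 5 genotypes, without an interaction of genotype and stage. Their shares therefore do not cover changes limited to some genotypes. Of the changes of 1.5, the stage tests recovered 97 to 100%, the genotype tests 74 to 90% and the interaction test 62%. The class tests on genotype means recovered 26, 23, 19, 14, 0 and 0% of them at the 6 days in order, 34% over the fibre stages and 0% for the transition. Of the changes of 3, the class tests recovered 71, 63, 65, 54, 27 and 27% by day, 81% over the fibre stages and 27% for the transition. Of the calls made, under 1% were false in the stage tests, 1.68 to 4.35% in the genotype tests and 8.93% (15 calls) in the interaction test. In the class tests 1.02, 2.27, 2.33, 2.86, 12.9 and 6.90% were false by day, 5.74% over the fibre stages and 3.57% for the transition, from 1 to 7 false calls each. The interaction test and the class tests at 19 and 25 dpa and over the fibre stages thus exceeded the nominal 5%. Camera recovered 20 of 20 shifted lists and called 0 of 80 that were not shifted.

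The alternatives were no offset with a floor at the 1st percentile (0.571), an offset at the 25th percentile (17.2), quantile normalization, median centring, no filter, a filter at the 60th percentile (200.455), no variance trend, no minimum change, each genotype left out, each array left out, the replicate number as a block, genotype as a random block with statmod 1.5.0, arrays as replicates for the classes, and 1 probe set per gene for the lists. The alternative without reporter and ribosomal RNA probe sets was added after the data had been seen. A position along the change from 6 to 25 dpa of the other 4 genotypes, projected over all tested probe sets, was computed for each array after the profiles had been seen. Arrays with a low BioC spike-in were set apart at the widest gap in the log2 difference of BioC and BioB, also after the values had been seen. For 12 and 19 dpa the position was computed again along the change of the genotypes without such arrays at 6 and 25 dpa. Other splits of the arrays or genotypes were counted for each comparison, with 100 random splits from a fixed seed where more existed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.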

Results

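The arrays measured 24132 probe sets in 89 samples of 5 genotypes, with 15 arrays at each of 0, 6, 9, 12 and 19 dpa and 14 at 25 dpa. Signals reached 40712.7. The correlation between replicates of a group had a median of 0.975 and a minimum of 0.90, the latter for JKC 725 at 12 dpa, replicate 2. Changes are on the log2 scale and are given with the standard error (SE) of limma, averaged over the 5 genotypes with n = 15 arrays per day, or 14 at 25 dpa. For the stage steps and the transition, this SE and the adjusted p measure the spread between replicate arrays of a group. They do not hold the spread between genotypes, which was large for many genes. Signals are MAS5 signals, given as the mean over genotypes with the SD over genotypes (n = 5).

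The step from the ovule at 0 dpa to fibre at 6 dpa asks which transcripts mark elongating fibre. KCS12, a 3-ketoacyl-CoA synthase for very long chain fatty acids, rose by 8.53 ± 0.16, from a signal of 17.1 ± 14 to 6660 ± 1355. The former lies below the filter's 40.4, so the size of this rise rests on the offset (9.17 without one and 7.67 with the larger one), as do those of XTH1, TUA10, PG and MYB5, which also had a mean signal below 40.4 on 1 of these days. XTH1, a xyloglucan endotransglucosylase that remodels the wall, rose by 7.88 ± 0.17, and the pectate lyase gene Pel rose by 6.46 ± 0.18. The alpha-tubulin gene TUA10 rose by 5.87 ± 0.20 and H6L by 5.74 ± 0.08. The largest falls were those of the polygalacturonase gene PG (-5.05 ± 0.24), the cyclopropane fatty acid synthase gene CPA-FAS-2 (-3.33 ± 0.28), the MYB factor genes MYB5 (-2.91 ± 0.32) and GHMYB36 (-2.85 ± 0.29), and CBP2 (-2.74 ± 0.23).

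Among the lists, 4 of the 5 probe sets for abundant fibre transcripts rose, including the fibre protein gene E6 (+2.28) and the expansin gene EXPA1 (+4.80), and camera called the list (adjusted p = 0.000333). This call was lost with an estimated correlation, at an adjusted p of 0.123. Of the 6 tubulin probe sets 5 rose (adjusted p = 0.000175, and 0.284 with an estimated correlation). Of the 17 fasciclin-like arabinogalactan probe sets, which encode cell surface proteins, 8 rose and 9 did not pass, with FLA4 at +2.97 (adjusted p = 0.0152, and 0.284 with an estimated correlation). Of the 4 actin probe sets 1 rose, ACT4 at +1.28 (adjusted p = 0.00241, and 0.286 with an estimated correlation). Camera also called the proteasome list as higher (median +0.43, adjusted p = 0.0335, and 0.214 with an estimated correlation), although no change among its 5 probe sets reached 1. In very long chain fatty acid synthesis 4 of 7 probe sets rose and 2 fell, the latter both assigned to KCS38 (-1.54 and -1.23), for which 2 other probe sets rose (+2.20 and +3.58). HIS2B, a histone gene used as a marker of dividing ovule cells, was at -0.18 and did not pass. Of the 2 tested members of the list of seed and embryo markers, the late embryogenesis gene Lea14-A was at +2.82 and Lea5-D at -0.80, under the minimum change.

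In all, limma called 4353 of 18659 probe sets (23.3%), 1588 higher and 2765 lower at 6 dpa. The division into higher and lower depended on the scaling of the arrays. The median change of all tested probe sets was -0.28 with the authors' scaling, -0.10 after quantile normalization, which gave 2057 higher and 1870 lower, and +0.02 after median centring, which gave 2430 higher and 1322 lower. The called changes of the genes named above all exceeded that shift.

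Within 6 to 12 dpa, planned as the elongation stages, Aux6 rose by 2.40 ± 0.14 from 6 to 9 dpa. Tubulin genes rose with it, TUA10 by 2.11 ± 0.20 and BTub1, a beta-tubulin gene that the tubulin list did not hold, by 1.73 ± 0.15. A probe set for CelA1, a cellulose synthase of the secondary wall, rose by 1.91 ± 0.30, and the chalcone synthase gene CHS3, of flavonoid synthesis, rose by 1.79 ± 0.10. CPA-FAS-2 changed by -1.83 ± 0.28, and the MYB factor gene GHMYB10 by -1.01 ± 0.27 (adjusted p = 0.00284), close to the minimum change. The GHMYB10 call was lost after quantile normalization (-0.94), with the larger offset (-0.94), and without JKC 725 or JKC 777 (-0.82 each). From 9 to 12 dpa the largest rises among those that held in all 5 genotypes were those of nst3, a NAC factor gene that switches on secondary wall formation (1.85 ± 0.19), FLA6 (1.80 ± 0.26), the sucrose synthase gene susC (1.54 ± 0.10) and TUA10 (1.41 ± 0.18 for a different probe set). The CelA1 probe sets (2.50 ± 0.30 and 2.04 ± 0.20) and another FLA6 probe set (1.95 ± 0.26) rose more on average, but not in all 5 genotypes. CPA-FAS-2 changed by -1.69 ± 0.28 and cdn1-C4, a cadinene synthase gene of the gossypol pathway, by -1.59 ± 0.28. GHMYB10 changed by -1.42 ± 0.27 and GHDEL61, annotated as a bHLH factor, by -1.08 ± 0.22, a call that was lost with the larger offset (-0.71) and without JKC 703 (-0.78).

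Of the lists, tubulins alone were called in both of these steps. From 6 to 9 dpa 2 of 6 probe sets rose (adjusted p = 0.000775, and 0.286 with an estimated correlation), and from 9 to 12 dpa again 2 of 6 (adjusted p = 0.00296, and 0.353 with an estimated correlation). The probe sets that rose in both steps were 2 of the 3 for TUA10, and the third was at +0.18 and +0.17 and was not called. In total 397 probe sets were called from 6 to 9 dpa, 257 higher and 140 lower, and 458 from 9 to 12 dpa, 236 higher and 222 lower. Without an offset the counts were 602 and 704, and with the larger offset the first was 255.

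From 12 to 19 dpa, FLA6 rose by 4.05 ± 0.26 and nst3 by 2.40 ± 0.19. The CelA1 probe set with the lower mean rose by 1.86 ± 0.20, while the other was at -0.13 and was not called. PAP10 rose by 1.46 ± 0.17 and Pat1 by 1.22 ± 0.15. Falls were led by the MYB factor gene myb109, which acts in fibre initiation and elongation (-2.44 ± 0.21), Pel (-2.20 ± 0.18), cdn1-C4 (-2.08 ± 0.28), CMDR1 (-2.01 ± 0.14) and a xyloglucan endotransglucosylase gene listed as XTH (-1.75 ± 0.15). From 19 to 25 dpa, the CelA1 probe set with the lower mean rose by 3.59 ± 0.20, while the other was at -0.60 and was not called. CTL1, a chitinase-like protein gene tied to cellulose deposition, rose by 3.14 ± 0.19. FLA7 rose by 3.07 ± 0.33, GLU by 2.48 ± 0.28 and the small GTPase gene Rac9 by 2.39 ± 0.21. Falls were those of myb109 (-2.46 ± 0.21), the expansin genes EXPA4 (-2.32 ± 0.16) and EXPA11A (-2.25 ± 0.13), cdn1-C4 (-2.12 ± 0.29) and Pel (-2.04 ± 0.19).

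Several of these means joined genotypes that changed strongly and genotypes that hardly changed. From 12 to 19 dpa Pel was at -4.51 in JKC 725, -5.80 in JKC 703, -0.034 in JKC 777, -0.49 in JKC 783 and -0.18 in JKC 737, and in the same order myb109 was at -4.91, -5.09, -1.06, -0.030 and -1.10 and CMDR1 at -4.55, -4.73, -0.13, -0.28 and -0.33. FLA6 had the opposite division, at +0.61, +0.067, +7.24, +5.32 and +7.03. In JKC 777 and JKC 737 its signal at 12 dpa was 7.24 and 9.11, below the filter's 40.4, so the sizes of these rises rest on the offset. The mean rise of FLA6 was 4.43 without an offset and 3.58 with the larger one in this step, and 7.42 and 6.09 in the transition. From 19 to 25 dpa the CelA1 probe set with the lower mean was at +0.37, +0.20, +7.05, +3.05 and +7.27, CTL1 at +0.59, +0.58, +6.28, +1.96 and +6.32, and FLA7 at +0.61, +0.57, +6.42, +0.87 and +6.87. The level of FLA7 at 19 dpa in JKC 777 and JKC 737 also lay below the filter, so the sizes of those rises rest on the offset. Rac9 and GLU also changed by under 1 in JKC 725 and JKC 703, and so did myb109 and cdn1-C4. In the earlier step from 6 to 9 dpa TUA10 was at +0.50, +0.58, +2.07, +3.63 and +3.77. The CelA1 probe set with the higher mean was at +0.58, +0.30, +1.30, +3.07 and +4.30 in this step. The one with the lower mean was at +0.49 over the genotypes and was not called.

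Expansins, which loosen the wall of growing cells, were lower in both steps, with 3 of 5 probe sets falling from 12 to 19 dpa (adjusted p = 0.000828, and 0.214 with an estimated correlation) and 4 of 5 from 19 to 25 dpa (adjusted p = 9.65e-05, and 0.123 with an estimated correlation). Of these 5 probe sets 3 were for EXPA4, so they are not independent. NAC factors were called as higher from 12 to 19 dpa, with 4 of 10 probe sets rising, 3 of them those of nst3 (adjusted p = 0.0196, and 0.427 with an estimated correlation). In total 1544 probe sets were called from 12 to 19 dpa, 749 higher and 795 lower. From 19 to 25 dpa 908 were called, 305 higher and 603 lower. The latter division also depended on scaling, with 363 higher and 437 lower after quantile normalization and 449 higher and 353 lower after median centring, for which the median change was -0.10, -0.01 and +0.08 in turn.

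**Figure D1:**
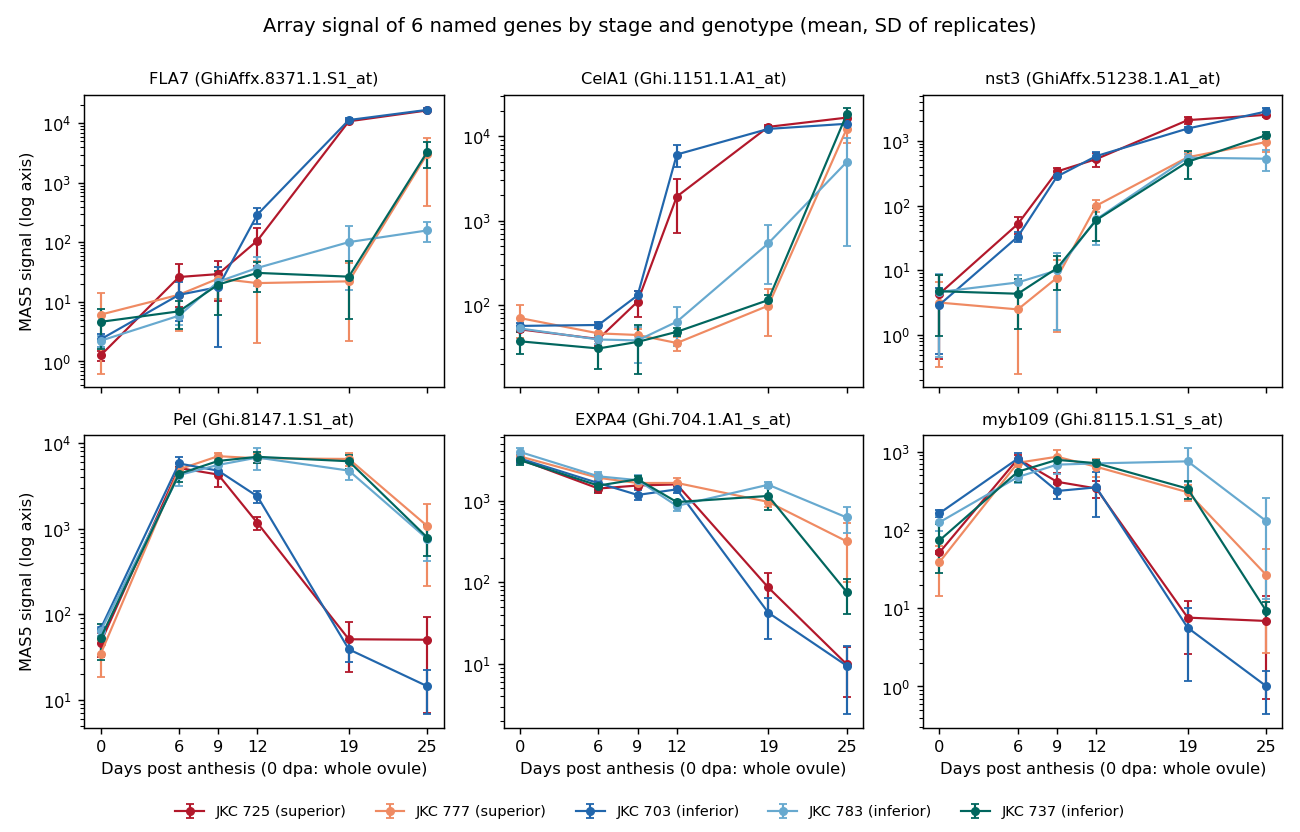
MAS5 signal (log axis) of FLA7, CelA1, nst3, Pel, EXPA4 and myb109 against days post anthesis, with a line per genotype joining the mean of 3 arrays (2 for JKC 783 at 25 dpa) and bars of 1 SD, the lower bars shortened where they would reach 0. Over the 5 genotypes the mean signal of CelA1, for which the probe set with the lower mean is drawn, went from 42.2 at 6 dpa to 13290 at 25 dpa and that of Pel from 4865 to 537.

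The transition contrast asks which transcripts differ between 6, 9 and 12 dpa, planned as the elongation stages, and 19 and 25 dpa, planned as those of wall thickening. Wall deposition itself was not measured, and the genotypes differed in the days on which such genes changed. FLA6 rose by 6.81 ± 0.17, FLA7 by 5.25 ± 0.21, CelA1 by 5.18 ± 0.13, nst3 by 4.44 ± 0.12 and susC by 3.95 ± 0.07. The largest falls were those of cdn1-C4 (-4.05 ± 0.18), myb109 (-3.84 ± 0.14), Pel (-3.50 ± 0.12), EXPA4 (-3.21 ± 0.10) and a probe set for the lipid transfer protein gene LTP3 (-3.19 ± 0.09). Limma called 3469 probe sets, 1642 higher and 1827 lower at the later stages. This division also depended on scaling, with 1804 higher and 1698 lower after median centring.

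Of the genes of cellulose and the wall, both CelA1 probe sets rose, which were the only tested members of the lists of secondary wall and of all cellulose synthases. For the second one (+1.87 ± 0.19) the genotypes moved in opposite directions, with changes of -2.24 in JKC 725, +4.87 in JKC 777, -2.94 in JKC 703, +4.37 in JKC 783 and +5.28 in JKC 737. CTL1, the only member of the cellulose deposition partners, rose by 3.71 ± 0.12. Of the sucrose cleavage genes 2 of 4 probe sets rose, susC and SusA1 (1.47 ± 0.16), while Sus1 was at -0.40. Fasciclin-like arabinogalactan proteins divided, with 5 of 17 probe sets higher and 5 lower, a median of -0.37 and a mean of +0.55, and camera placed the list lower at an adjusted p of 0.998. FLA4, whose probe set had the highest mean of the list, was at +0.94 and did not reach the minimum change.

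Of the genes of wall loosening and elongation, all 5 probe sets on the expansin list fell, with a median of -2.74 (adjusted p = 0.00575, and 0.286 with an estimated correlation). The list held EXPA1, EXPA4 (3 of the 5 probe sets) and EXPA11A but not EXPA3D, for which 1 of 2 probe sets fell and 1 was not called. Among them EXPA11A fell by 3.18 ± 0.08 and EXPA1 by 1.15 ± 0.07. The EXPA1 call rested on JKC 725 (-3.50) and JKC 703 (-3.88), since the other 3 genotypes were at +0.47 to +0.62, and it was lost without either (-0.57 and -0.47). Xyloglucan endotransglucosylases had 1 of 5 probe sets higher (XTH3, +1.48 ± 0.17), 1 lower (XTH, -2.51 ± 0.10) and 3 not called, XTH1 among them (+0.48). In pectin modification Pel fell and PG was not called. Of the very long chain fatty acid genes 4 of 7 probe sets fell, including those of KCS38 (-2.02 ± 0.08 and -1.34 ± 0.08) and KCS45 (-1.64 ± 0.08). The call for the first KCS38 probe set was lost without JKC 703 (-0.90), and that for the second without JKC 725 (-0.83) or JKC 703 (-0.66). Of the lipid transfer protein probe sets 1 fell and 1 did not pass, both assigned to LTP3, the latter at +0.24 and at -0.070 after quantile normalization. Tubulins had 2 of 6 probe sets higher, both for TUA10 (+2.16 ± 0.12 and +2.13 ± 0.13), and no actin probe set passed. TUA6 was at +0.12 and the actin gene ACT1 at +0.21, and both changed sign after quantile normalization (-0.18 and -0.14). For turgor and vacuole 0 of 2 probe sets passed, with the phosphoenolpyruvate carboxylase gene PEPC1 at -0.32. Fibre cell markers had 2 of 5 probe sets lower, LTP3 and EXPA1. For fibre-named genes 0 of 2 passed, with E6 at -0.01, a value near 0 whose sign changed with median centring (+0.040).

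Of the hormone and redox genes, ethylene synthesis had 2 of 6 probe sets higher, including the ACC oxidase gene ACO3 (+1.51 ± 0.21), and 1 lower, the ACC synthase gene ACS3 (-1.55 ± 0.12), with ACS1 at +0.10. The auxin response list had 1 of 3 lower, which was LTP3, listed through a synonym and not known as an auxin response gene. DET2, a steroid reductase gene of brassinosteroid synthesis and the only tested member of its list, changed by -1.77 ± 0.05. The catalase gene CAT2 rose by 1.12 ± 0.08, a call that was lost with the larger offset (+0.95). Class III peroxidases had 2 of 6 higher, among them pod10 (+1.73 ± 0.25), and 1 lower (-2.10 ± 0.16). Of the glutathione S-transferases 1 probe set rose (+1.80 ± 0.26) and 1 fell (-2.02 ± 0.08). In flavonoid synthesis CHS3 rose (+1.80 ± 0.07), DFR fell (-1.19 ± 0.05) and 3 did not pass. The DFR call was lost without JKC 725 (-0.97) or JKC 703 (-0.86). In phenylpropanoid synthesis CCR1 did not pass at -0.25, and was at +0.23 without JKC 703.

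Of the regulators, 4 of 9 MYB probe sets fell, including myb109 and GHMYB10 (-2.94 ± 0.18), and 1 of the 2 GHMYB38 probe sets (-1.97 ± 0.12), while the other, with the higher mean, was at -0.76 and was not called. NAC factors had 5 of 10 higher, of which nst3 had +4.44 and +4.10, and 1 lower, with NAC2 at +0.53. HD-ZIP factors had 0 of 2 called, with HOX3, which promotes fibre elongation, at -0.39. WRKY factors had 0 of 3 called, with WRKY15 at +0.28 and at -0.086 without JKC 703. No member passed among 4 annexin and 14-3-3 probe sets (AnnGh1 +0.17, and -0.17 after quantile normalization), 4 for ribosomal proteins (RPL37A -0.58), 5 for the proteasome (paC1 +0.96), 4 for calcium signalling (CBL2 -0.76) and 2 for dividing cells (HIS2B -0.35). Of the seed and embryo genes Lea5-D rose (+1.82 ± 0.18) and Lea14-A fell (-1.36 ± 0.11, and -0.99 without JKC 725, which was not called). No probe set matched the lists of secondary wall polymers, heat shock proteins, protein breakdown, photosynthetic tissue, or pollen and flower parts. Camera called expansins alone in this contrast.

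The median, the mean and the camera test of a list differed in sign in some of the tests, none of them called. From 0 to 6 dpa these were expansins, sucrose cleavage, ethylene synthesis, peroxidases, NAC factors and calcium signalling. From 6 to 9 dpa they were expansins, flavonoid synthesis and calcium signalling, and from 9 to 12 dpa very long chain fatty acid synthesis, ethylene synthesis, auxin response, peroxidases, WRKY factors and fibre cell markers. From 12 to 19 dpa they were fasciclin-like proteins, xyloglucan endotransglucosylases, auxin response, the proteasome and calcium signalling, and from 19 to 25 dpa fasciclin-like proteins, ethylene synthesis, auxin response, WRKY factors and calcium signalling. In the transition they were fasciclin-like proteins, xyloglucan endotransglucosylases, auxin response, annexins and calcium signalling, and between the classes xyloglucan endotransglucosylases, tubulins, flavonoid synthesis and NAC factors.

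The levels of many of these genes differed among the 5 genotypes on the same day. FLA6 was at 10.38 and 10.21 on the log2 scale in JKC 725 and JKC 703 at 9 dpa, and at 3.27, 4.29 and 3.23 in JKC 777, JKC 783 and JKC 737. At 12 dpa the CelA1 probe set with the lower mean was at 10.60 and 12.53 in JKC 725 and JKC 703 and at 5.29, 5.98 and 5.70 in JKC 777, JKC 783 and JKC 737, and susC was at 12.23 and 12.77 against 9.27, 7.92 and 9.24 in the same order. At 19 dpa, when FLA7 was at 13.40 and 13.47 in JKC 725 and JKC 703 and at 4.33, 6.44 and 4.68 in the other 3, Pel was at 5.67 and 5.41 against 12.65, 12.19 and 12.56. At 25 dpa KCS38 was at 6.86 and 6.00 in JKC 725 and JKC 703 and at 12.89, 13.22 and 12.91 in JKC 777, JKC 783 and JKC 737.

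At 0 dpa the largest range among nameable genes was that of the GHMYB38 probe set with the higher mean, at 6.61 in JKC 725, 6.38 in JKC 703, 10.58 in JKC 777, 9.89 in JKC 783 and 9.72 in JKC 737 (adjusted p = 6.1e-19). The ranges of TUA10 (3.47), PG (3.35), FLA6 (3.15) and FLA13 (2.68) followed, of which that of FLA6 was lost without JKC 725 (0.65) and that of PG without an offset (adjusted p = 0.0576). At 6 dpa the largest range was that of a CelA1 probe set, at 11.69 in JKC 725, 11.72 in JKC 703, 4.88 in JKC 777, 4.56 in JKC 783 and 4.11 in JKC 737 (adjusted p = 2.97e-20), ahead of TUA10 (5.48), WRKY71 (5.22), EXPA3D (4.27) and a peroxidase gene (4.27). After FLA6 and CelA1 at 9 dpa came nst3, XTH3 and CPA-FAS-2, with ranges of 5.49, 5.05 and 4.82, and at 12 dpa cdn1-C4 (5.38) and CTL1 (5.38). At 19 dpa EXPA3D, CelA1 and CTL1 had ranges of 7.69, 7.18 and 7.15, and at 25 dpa EXPA11A, Aux6, FLA7 and EXPA3D had 6.80, 6.79, 6.73 and 6.69. The F test of limma called 5338 probe sets at 0 dpa, 5249 at 6 dpa, 4813 at 9 dpa, 5665 at 12 dpa, 9204 at 19 dpa and 9261 at 25 dpa, or 28.6% of those tested at 0 dpa and 49.6% at 25 dpa.

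The interaction of genotype and stage over the fibre stages was called for 14825 probe sets (79.45%). The largest ranges of the transition change among nameable genes were those of Aux6, CelA1, GLU, EXPA3D and KCS38. Aux6 changed by -3.78 in JKC 725, -4.65 in JKC 703, +3.79 in JKC 777, +3.53 in JKC 783 and +2.83 in JKC 737 (adjusted p of the interaction = 1.53e-37). GLU changed by +6.05, +5.42, +0.34, -1.70 and +1.24 in the same order, and EXPA3D by -5.94, -5.80, +0.07, +1.56 and -0.58. From 12 to 19 dpa 3669 probe sets were called in JKC 725, 5407 in JKC 703, 1682 in JKC 777, 1588 in JKC 783 and 1531 in JKC 737. From 19 to 25 dpa the counts were 1224, 1068, 2161, 791 and 3337 in the same order, the JKC 783 count resting on 2 arrays at 25 dpa.

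**Figure D2:**
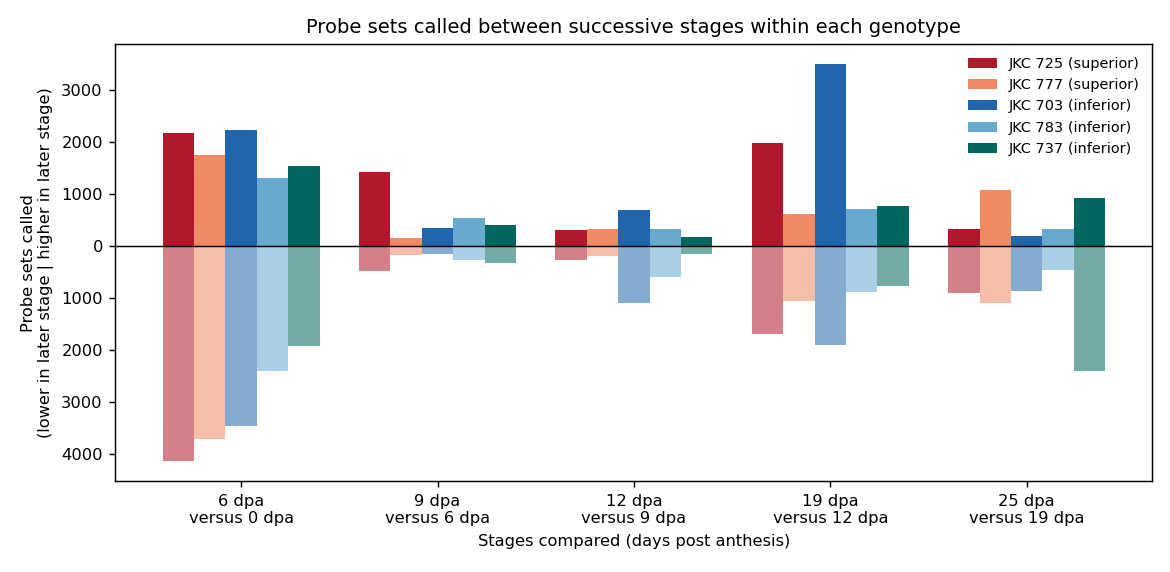
Number of probe sets called in each stage step, by genotype, with bars upwards for probe sets higher at the later day and downwards for those lower. From 12 to 19 dpa JKC 703 had 3504 higher and 1903 lower, and JKC 737 had 773 higher and 758 lower.

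The mean log2 signal of the hybridisation spike-ins also differed between genotypes, at 10.23 ± 0.60 (SD, n = 18 arrays) in JKC 725, 10.43 ± 0.49 in JKC 703, 11.08 ± 0.32 in JKC 777, 10.98 ± 0.31 (n = 17) in JKC 783 and 11.02 ± 0.39 in JKC 737. The log2 ratio of the actin control probe sets at the 3' and 5' ends, a sign of RNA integrity, was 2.22 ± 0.59, 2.23 ± 0.77, 2.60 ± 0.53, 2.82 ± 0.67 and 2.68 ± 0.67 in the same order. These means over the days hide a turn, since at 6 dpa the ratio was 1.66, 1.44, 2.86, 3.27 and 3.32 in that order and at 25 dpa 3.11, 3.06, 2.48, 2.23 and 2.36. Over all genotypes the ratio also moved with stage, at 3.21, 2.51, 1.98, 2.13, 2.53 and 2.68 from 0 to 25 dpa, and the spike-in signal went from 10.43 to 11.18, so the stage steps also join arrays that differ in these measures. In 16 of the 89 arrays the BioC spike-in lay unusually low against BioB, at a log2 difference of -0.37 to 0.0056 where the others had 1.09 to 1.46. These were all arrays of JKC 725 at 9 and 25 dpa, of JKC 703 at 25 dpa and of JKC 777 and JKC 737 at 0 dpa, and 1 of 3 of JKC 783 at 0 dpa. No array of 6, 12 or 19 dpa was among them.

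**Figure D3:**
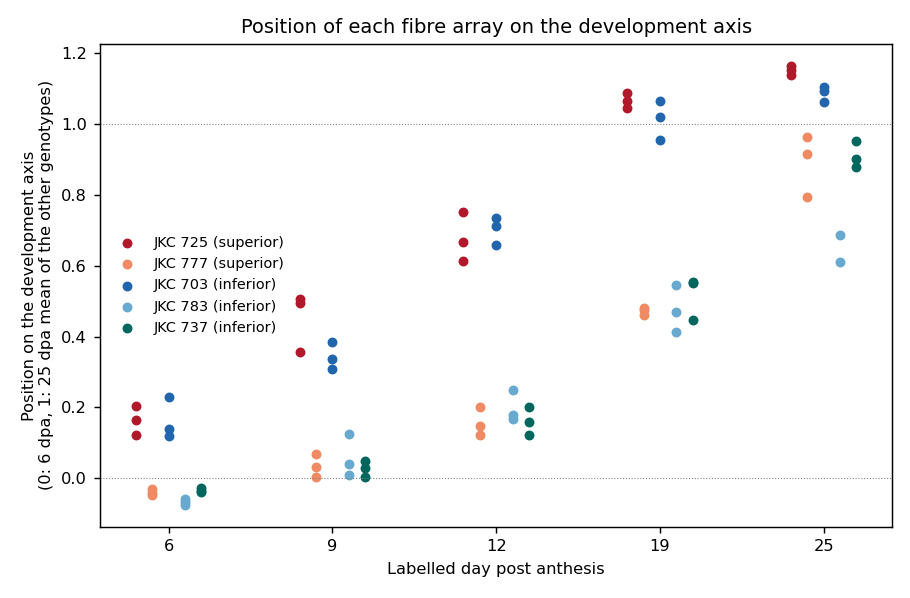
Position of each fibre array along the change from 6 to 25 dpa of the other 4 genotypes (0 is their 6 dpa mean and 1 their 25 dpa mean), against days post anthesis, with 1 point per array coloured by genotype. The axis was built anew for each genotype, so positions of different genotypes are not on a common scale. At 19 dpa the means were 1.07 for JKC 725, 1.01 for JKC 703, 0.472 for JKC 777, 0.476 for JKC 783 and 0.517 for JKC 737.

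The comparison of superior with inferior genotypes asks which transcripts go with fibre quality. Over the fibre stages, XTH1 was 0.46 ± 0.23 higher in the superior genotypes, a peroxidase gene 0.44 ± 0.24, the galactosyltransferase-named gene GalT1 0.29 ± 0.15 and GHTTG1, a WD-repeat regulator of epidermal cell fate, 0.27 ± 0.17 higher (SE over genotypes, n = 2 and 3). The differences for RacA, BC1, ASP3 and psmB1 were between 0.13 and 0.20. A probe set for GHMYB38 was at -0.82 ± 0.20 relative to the inferior genotypes (the other, with the higher mean, was at -0.22 ± 0.89), Aux3 at -0.70 ± 0.25, CAT2 at -0.58 ± 0.25, the ion channel gene CNGC2 at -0.58 ± 0.25 and CLP at -0.51 ± 0.26. Aux2, SCP, MYB1, VP and CPR2 were between -0.46 and -0.32. None of these differences passed the test with genotypes as replicates (adjusted p = 1 for each).

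On single days the genes with separated classes also failed the correction. At 0 dpa these were the chalcone synthase gene CHS6 (+1.55 ± 0.40), KCS12 (+1.38 ± 0.51), MPK3 (+0.87), Aux6 (+0.69), MFS (+0.66), myb109 (-1.29 ± 0.47), Glp1 (-0.85), SCP (-0.81), POX9 (-0.71) and MADS-9 (-0.66). The signal of KCS12 at 0 dpa was near background, and its difference was +2.05 without an offset and +0.81 with the larger one. At 6 dpa the separated genes were GID1-4 (+0.57), NAC7 (-0.91 ± 0.31), the GHMYB38 probe set with the lower mean (-0.82 ± 0.24), CLP (-0.77) and SKD1 (-0.32). At 9 dpa that GHMYB38 probe set was at -1.28 ± 0.25 and RAV1 at -1.83 ± 0.81, with MYB6, PAP1 and LEGB between -0.56 and -0.45, and the lipoxygenase gene Lox1 at +0.63 ± 0.23, GHTTG1 at +0.34 and GalT1 at +0.33. At 12 dpa the kinase gene MPK14 was at +0.68 ± 0.31, a probe set for EXPA4 at +0.66 ± 0.27, sad1 at +0.42, WD1521 and psmB1 at +0.25 and +0.24, CAT2 at -0.66 ± 0.29, CLP at -0.63, RHM3 at -0.49 and CCR1 at -0.46. At 19 dpa GHDEL61 was at +0.99 ± 0.38, CBP2 at -1.35 ± 0.53, CAT2 at -0.67 and CLP at -0.45. At 25 dpa the proteasome gene paC1 was at +0.34 ± 0.23, Aux3 at -1.55 ± 0.45, SCP at -0.93 ± 0.22, Aux2 at -0.60, CANT1 at -0.59 and EF1A7 at -0.47.

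Of the gene lists, MYB factors were lower in the superior genotypes over the fibre stages (median -0.27, adjusted p = 0.0191, and 0.353 with an estimated correlation) while limma called no single member. The median of this list was -0.28 after quantile normalization. The 18 other lists were not called, with fasciclin-like proteins at a median of -0.23 (adjusted p = 0.12) and WRKY factors at -0.28 (adjusted p = 0.144).

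The few probe sets that limma called were all lower in the superior genotypes, and they are given after their values had been seen. An unnamed probe set was at -3.91 ± 0.20 at 0 dpa (adjusted p = 0.00703) and at -3.49 ± 0.21 at 6 dpa (adjusted p = 0.0243). At 0 dpa it was at 7.21 in JKC 725 and 7.0 in JKC 777, and at 11.26 in JKC 703, 10.98 in JKC 783 and 10.78 in JKC 737. A probe set paired with the gene LOC107904077 was at -4.78 ± 0.23 (adjusted p = 0.0112) and another unnamed one at -6.33 ± 0.26 (adjusted p = 0.00826) at 6 dpa. A further unnamed probe set was at -5.10 ± 0.24 at 12 dpa (adjusted p = 0.042). The first 3 separated the classes on all 6 days, with differences of -1.87 to -3.91, -3.16 to -5.27 and -3.89 to -6.33. The last did so on 5 days and was at -0.94 at 25 dpa. In the superior genotypes the probe set with -6.33 was at 3.17 and 3.34 and that with -5.10 at 3.85 and 3.99, below the filter's 5.49 on this scale, so the sizes of these differences rest on the offset.

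Limma called 1 probe set at 0 dpa, 3 at 6 dpa, 0 at 9 dpa, 1 at 12 dpa, 0 at 19 dpa and 0 at 25 dpa, and 0 both over the fibre stages and for the class difference in the transition. At an unadjusted p under 0.05 these counts were 680, 199, 326, 242, 77, 94, 133 and 50 in the same order. The classes did not overlap in 16.9% of probe sets at 0 dpa, 9.93% at 6 dpa, 13.5% at 9 dpa, 12.6% at 12 dpa, 7.22% at 19 dpa, 7.93% at 25 dpa, 8.34% over the fibre stages and 5.85% for the transition, where chance gives 20%. The 3 calls at 6 dpa fell to 0 without JKC 725, JKC 777, JKC 783 or JKC 737, and the call at 12 dpa was lost without any 1 of the 5 genotypes. The call at 0 dpa was lost without JKC 777, while 12 were made without JKC 725.

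**Figure D4:**
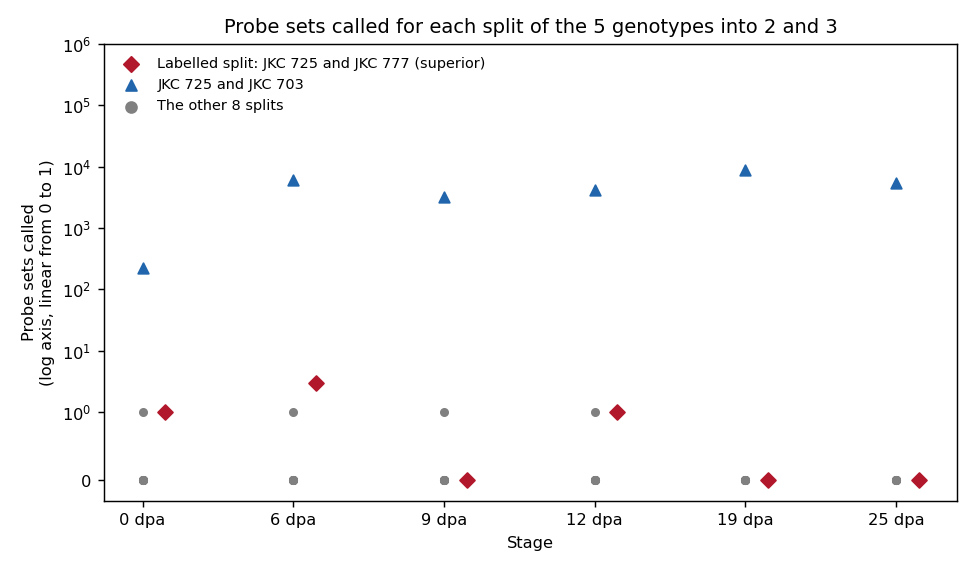
Number of probe sets called by limma (log axis) for each of the 10 ways to set 2 genotypes against 3, on each day, with the diamond for the labelled classes, the triangle for JKC 725 and JKC 703 against the others, and grey points for the other 8 splits. At 19 dpa the labelled classes gave 0 calls and JKC 725 and JKC 703 against the others 8827.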

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

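The tests weighed here had their outcomes stated in advance, but the position along the 6 to 25 dpa change, the search for the best matching day and the test of arrays with a low BioC spike-in were chosen after the profiles had been seen, and the SD over genotypes was taken as the spread of the variance share after that share was known.

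The genotypes changed differently over the 5 fibre stages, by a test of the interaction itself without a minimum change, for 14825 probe sets. Among nameable genes the transition change of Aux6 ranged over 8.44 on the log2 scale between genotypes, that of the CelA1 probe set with the higher mean level over 8.21, that of GLU over 7.75, that of EXPA3D over 7.49 and that of KCS38 over 7.19. At 6 dpa the signal of that CelA1 probe set in JKC 777, JKC 783 and JKC 737 lay below the filter's 40.4, and so did that of EXPA3D at 19 and 25 dpa in JKC 725 and JKC 703. The sizes of their ranges therefore rest on the offset, at 8.39 and 8.20 without one and 7.88 and 6.60 with the larger one. That probe set for CelA1, a cellulose synthase gene of the secondary wall, was at 11.69 and 11.72 in JKC 725 and JKC 703 at 6 dpa. Its transition change was -2.24 and -2.94 in these and +4.87, +4.37 and +5.28 in JKC 777, JKC 783 and JKC 737. The other CelA1 probe set rose in the transition in all 5 genotypes, by 6.25 in JKC 725, 5.17 in JKC 703, 4.52 in JKC 777, 4.76 in JKC 783 and 5.21 in JKC 737. The probe sets also differed from 0 to 6 dpa, where the mean over genotypes was +3.18 for the former and -0.31, not called, for the latter. A high level of CelA1 at 6 dpa therefore rests on 1 of its probe sets. For this interaction 1 of 100 splits of the arrays, the real one, gave as many calls (highest other 5826). These splits dealt genotypes anew within each stage and so also broke up level differences that hold over all stages. They speak against chance for genotype differences of any kind, but cannot exclude it for the interaction alone.

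The fibre profiles of the genotypes also stood at different points on the same day, each measured against the change of the others. That change was taken anew for each genotype, so these positions are not on a common scale. On a scale where 0 is the other genotypes' 6 dpa and 1 their 25 dpa, JKC 725 was at 0.677 ± 0.070 (SD, n = 3) at 12 dpa and at 1.07 ± 0.02 at 19 dpa, JKC 703 at 0.702 ± 0.039 and 1.01 ± 0.06, JKC 777 at 0.158 ± 0.040 and 0.472 ± 0.010, JKC 783 at 0.198 ± 0.044 and 0.476 ± 0.066, and JKC 737 at 0.161 ± 0.039 and 0.517 ± 0.061. The profile of JKC 725 at 12 dpa correlated better with JKC 777, JKC 783 and JKC 737 at 19 dpa (r over probe sets 0.953, 0.962 and 0.958) than with the same genotypes at 12 dpa (0.932, 0.931 and 0.926), and genes are not independent replicates.

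Of the 9204 probe sets called between genotypes at 19 dpa, 84.4% were also called after quantile normalization, above the bound of 80% set in advance. This argued against the scaling of the arrays as the whole cause of those calls. RNA degradation or hybridisation efficiency as the whole cause of those calls was argued against as well. With each array's spike-in level and actin ratio as covariates, which were themselves associated with 5813 probe sets, 86.8% were also called. The covariates' slopes came from the spread between replicates of a group, so this counts against that cause only as far as the same slopes hold between groups. Positions along the axis were computed again neither after quantile normalization nor with these covariates. At 6 and 25 dpa, which set the axis, the actin ratio divided JKC 725 and JKC 703 from the others. For the positions, scaling and RNA integrity therefore stay open. A batch marked by the low BioC spike-in took in 16 arrays of 0, 9 and 25 dpa, and the positions were computed again without them. With no such array in the axis or at 19 dpa, the positions at 19 dpa were 0.981 in JKC 725, 0.907 in JKC 703, 0.696 in JKC 777, 0.640 in JKC 783 and 0.736 in JKC 737, a range of 7.07 times the pooled SD of replicates. The mark is argued against as the whole cause of these values, which used no marked array. The axis was again built anew for each genotype, so their range does not give differences on a common scale. At 12 dpa the positions were 0.725, 0.764, 0.348, 0.340 and 0.366 in the same order. The differences between these genotypes were smaller on these axes, and the 12 dpa positions of JKC 777, JKC 783 and JKC 737 were over 1.5 times those on the former axes. The match of JKC 725 at 12 dpa with the others at 19 dpa used no marked array either. For the values at 0, 9 and 25 dpa and the steps that use them, this mark goes with whole groups of genotype and day, so a part of those differences cannot be told apart from it. An earlier course of fibre development in some genotypes may account for a part of the pattern, as 22.9% of the variance between genotypes at 19 dpa lay along the 6 to 25 dpa change of the others, and most of the variance lay off it. That share was under the lower bound of 25% set in advance, but by less than its spread over genotypes (SD 5.76), so it decided neither way. By genotype it ran from 14.5% in JKC 703 to 29.0% in JKC 777, on both sides of the bound. The axis is a straight line, so on a curved course a shift in timing alone would also fall partly off it. The variance off the axis therefore does not speak against timing. Growing conditions or dates that differed between genotypes, and other processing of arrays genotype by genotype, are not given in the labels and stay open as untested. So does an exchange of genotype labels or of sampling days, which would change what the comparison of superior with inferior genotypes means, as do differences of the genotypes themselves that are not ones of timing.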

How the results depend on the processing

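The tests without reporter and ribosomal RNA probe sets were chosen after the data had been seen, and under them all 22 counts and 196 values of named genes kept their direction and their side of the threshold. The stage, genotype and interaction counts stayed within 1.5 times the main count under every alternative except those given here. Without an offset, 602 probe sets were called from 6 to 9 dpa and 704 from 9 to 12 dpa. With the offset at the 25th percentile 255 were called from 6 to 9 dpa. With the filter at the 60th percentile 2829 were called between genotypes at 0 dpa, where fewer probe sets were tested. Without JKC 725, 3117 were called between genotypes at 9 dpa, and without JKC 777 2939 at 0 dpa, from fewer genotypes. With no minimum change the calls were 14043, 6190, 6597, 9938 and 7484 for the 5 steps in order, 15065 for the transition, and 9716, 9554, 9202 and 10108 between genotypes at 0, 6, 9 and 12 dpa. No single array moved any of these counts by over 1.5 times. For the offsets the cause was not tested.

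The class counts were small and changed more readily, and the cause was not tested. At 0 dpa, where 1 was called, the count was 2 without an offset, 3 with median centring, without a filter, without the variance trend and without JKC 783, 12 without JKC 725 and 0 without JKC 777. At 6 dpa, where 3 were called, it was 0 without JKC 725, JKC 777, JKC 783 or JKC 737. At 12 dpa, where 1 was called, it was 0 with the offset at the 25th percentile, quantile normalization, the filter at the 60th percentile, and without JKC 725, JKC 703, JKC 777, JKC 783 or JKC 737. Leaving out single arrays gave 1 to 4 calls at 0 dpa (4 without JKC 783 at 0 dpa replicate 1, and 3 without JKC 725 or JKC 777 at 0 dpa replicate 3), 0 to 1 at 9 dpa (1 without JKC 783 at 9 dpa replicate 1), 0 to 1 at 12 dpa (0 without JKC 725 replicate 1 or 2, JKC 777 replicate 1 or JKC 737 replicate 1 of that day) and 0 to 2 over the fibre stages (2 without JKC 725 at 25 dpa replicate 3). With genotype as a random block the calls were 7, 5, 5, 6 and 4 from 0 to 19 dpa, 23 over the fibre stages and 19 for the transition. With arrays counted as replicates, which takes arrays of 1 genotype as independent, they were 2802, 2160, 1574, 2043, 1977 and 2989 by day, 5181 over the fibre stages and 1986 for the transition. With a difference of at least 1 as well they were 306, 267, 297, 286, 354, 476, 124 and 231 in the same order. Of the 12 list calls, 0 were made with an estimated correlation, and 7 were made with 1 probe set per gene, 6 of them shared.

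Among named genes, signs reversed for values that had not been called in the transition. After quantile normalization TUA6 was at -0.18, ACT1 at -0.14, the LTP3 probe set with the higher mean at -0.070 and AnnGh1 at -0.17. E6 was at 0.040 with median centring, 0.14 without JKC 725 and 0.17 without JKC 703, and between -0.039 and 0.013 with each array left out. Without JKC 703 CCR1 was at 0.23 and WRKY15 at -0.086. The call of GHMYB10 from 6 to 9 dpa was lost with 12 of the 89 arrays left out in turn and that of GHDEL61 from 9 to 12 dpa with 3, where both lay close to the minimum change. Replicate numbers did not pair the arrays across groups, as all same-number correlations were above 0.1 in 5 of 435 group pairs and 35 of 89 arrays matched their own number best. With the replicate block the step from 0 to 6 dpa had 4354 calls and that from 19 to 25 dpa 906. Depth is set by signal over background. The array medians of 59.94 to 119.8 lie near the filter's signal of 40.4, so changes of weak transcripts rest on the offset.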

Other observations

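The splits of the samples were planned, and the comparison of probe sets of 1 gene was made after its values had been seen.

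Probe sets assigned to 1 gene did not always move together. From 0 to 6 dpa 2 KCS38 probe sets were at +3.58 and +2.20 and 2 others at -1.54 and -1.23. In the transition, LTP3 was at -3.19 for 1 probe set and at +0.24 for the other, which had a mean log2 level of 13.49 against 10.21. From 19 to 25 dpa CelA1 was at +3.59 for 1 probe set and at -0.60 for the other. For TUA10, 2 of 3 probe sets were called as higher in the transition (+2.16 and +2.13) and the third was at +0.40. Of the fasciclin-like genes, FLA15 was at +1.36 and FLA2 at +1.64 in the transition, while FLA11, FLA12 and FLA13 were at -2.05, -2.30 and -2.47.

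For each stage comparison 1 of 100 splits of the arrays within genotypes, the real one, gave as many calls. This speaks against chance as far as 100 splits can, but does not exclude it. Dealing the labels anew also moved real differences into the spread between replicates, so the other splits do not show data without differences. The real count and the highest other were 4353 and 1109 from 0 to 6 dpa, 397 and 65 from 6 to 9 dpa, 458 and 139 from 9 to 12 dpa, 1544 and 587 from 12 to 19 dpa, 908 and 340 from 19 to 25 dpa, and 3469 and 354 for the transition. The same held for the genotypes on each day, with 5338 and 2713 at 0 dpa, 5249 and 3833 at 6 dpa, 4813 and 3110 at 9 dpa, 5665 and 4092 at 12 dpa, 9204 and 7586 at 19 dpa, and 9261 and 6584 at 25 dpa.

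The 10 ways to set 2 genotypes against 3 are too few for a share under 0.05. As many calls as for the labelled classes came from 3 splits at 0 dpa, 2 at 6 dpa, 10 at 9 dpa, 3 at 12 dpa, and 10 each at 19 dpa, at 25 dpa, over the fibre stages and for the transition. The real count and the highest other were 1 and 221 at 0 dpa, 3 and 6059 at 6 dpa, 0 and 3202 at 9 dpa, 1 and 4150 at 12 dpa, 0 and 8827 at 19 dpa, 0 and 5460 at 25 dpa, 0 and 8398 over the fibre stages, and 0 and 9689 for the transition. Each highest count came from JKC 725 and JKC 703 against the others, which points to a structure of the samples that the labelled classes do not follow. The classes were separated the same way on all 6 days in 15 probe sets, 4 higher and 11 lower in the superior genotypes, and 6 of the 10 splits gave as many (highest other 617, again JKC 725 and JKC 703).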
